A study of Homo sapiens with 4 samples.

How the data were processed

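Bulk RNA was measured in 4 libraries, 1 for each combination of 2 human cancer cell lines and 2 constructs. HCT-116 is a colorectal cancer line and MCF-7 is a breast cancer line. Per the series design, the cells were transduced to overexpress full-length p53β, a splice form of the tumour suppressor p53 with an alternative carboxyl end, or a stop-lost form of p53β. The labels mark each library as WT or BSL and do not spell out the codes. BSL was read here as the stop-lost form and WT as full-length p53β, and the libraries are named by their labels. All 4 libraries carry the treatment label medium, and none is labelled as untransduced or as a vector control. The labels do not settle whether WT is such a control, and neither do the TP53 counts.

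Per the labels' protocols, RNA was isolated with a column kit. The same protocol text names an oligo-dT cDNA step and a stranded total RNA library kit with ribosomal RNA removal. Which of them fed the sequencing libraries is not given in the sources used here. The deposited values are whole-number counts of fragments per gene, 1 file per library, not normalised. Per the submitters' processing notes, STAR 2.7.5a, HTSeq 0.12.4 and the hg38 genome build were used. The annotation release and the strand setting of the counting are not given in the sources used here. Each file also holds 5 tally rows for fragments that were not assigned to a gene. These took 48.3% of the fragments in HCT-116 WT, 48.9% in HCT-116 BSL, 43.3% in MCF-7 WT and 44.9% in MCF-7 BSL, and they were left out of library sizes and tests. Unaligned fragments made up 23.9%, 26.0%, 13.2% and 13.0% of the fragments in that order.

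The files list 60612 gene identifiers. Symbols were found for 60401 of them, and 58394 matched GENCODE 29 on the identifier without its version. Coordinates, gene types, exon overlap and GC content came from GENCODE 29 (GRCh38, the same assembly as hg38). Counts were analysed in R 4.3.3 with edgeR 4.0.16. Libraries were scaled by TMM factors, and log2 CPM (counts scaled to a common library size) were computed with a prior count of 2.

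Within each line there is 1 library per construct. The comparison of BSL with WT therefore has no replicate check and no p-value. A gene was measured in a line when its mean CPM over the 2 libraries was at least 1, and it was counted as higher or lower when its log2 ratio was at least 1 in size. Each ratio has an exact Clopper-Pearson 95% interval from its 2 counts. These intervals, and the exact Poisson intervals of single levels, cover counting error only, since each group has 1 library. The fragments carried no molecular identifiers, so duplicate copies may make the intervals too narrow even for counting error. A count of 0 allows up to 3 counts, which is 0.195, 0.211, 0.17 and 0.213 CPM in HCT-116 WT, HCT-116 BSL, MCF-7 WT and MCF-7 BSL. The expected number of 2-fold differences from counting error alone was averaged over 100 binomial splits of each gene's counts.

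The replicated test used all 4 libraries. An edgeR quasi-likelihood model with cell line and construct terms was fitted to the 15403 genes that passed filterByExpr, with Benjamini-Hochberg adjustment at a false discovery rate of 0.05. The test was two-sided. It treats the 2 lines as the repeats of a common construct effect and leaves 1 residual degree of freedom. The labels do not say whether the libraries came from separate cultures, so its p-values concern these libraries only. The fit moderates each gene's spread with spread pooled over all genes tested. Its p-values and standard errors therefore rest partly on that pooled spread and not on the 1 residual degree of freedom alone. On simulated counts for this comparison over 15403 genes, the test recovered 75 of 100 genes changed 2-fold and 48 of 100 changed 1.5-fold, with 7 false calls.

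Before the data were examined, 40 gene lists were fixed from textbook knowledge, covering p53 targets, cell cycle, stress responses, metabolism, signalling and markers of the cell lines and of other cell types. In each line, 36 lists had at least 5 measured members. Each list has its median log2 ratio, the number of members at least 1.5-fold higher or lower, and the percentile of its median among 10000 random lists of the same size matched on expression in 20 bins. The percentile describes these libraries and is not a test. Of the 36 lists, 15 lay outside the central 95% of random lists in HCT-116 and 17 in MCF-7. Random lists do not keep together genes that vary together, so an extreme percentile was common here. The rule for named genes was fixed at the same time. It takes TP53, MDM2 and CDKN1A. It takes the 12 highest and 12 lowest protein-coding genes per line among those with a mean CPM of at least 5, a log2 ratio of at least 1 in size and an interval that leaves out equality. It also takes the 10 protein-coding genes per direction that moved furthest in both lines, up to 10 genes per direction from the edgeR test, and up to 4 members per described list, with any member that went against its list by at least 1 on the log2 scale. A list was described when its median lay outside the central 95% of random lists in a line, or when it concerned p53, the cell cycle, oxidative phosphorylation or the unfolded protein response. That rule for describing lists was set after the list medians had been seen.

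Alternatives fixed beforehand were DESeq2 size factors, total counts without factors, other filters and prior counts, protein-coding genes alone, DESeq2 1.42.0, limma-voom (limma 3.58.1), a robust edgeR fit and a fit without the cell line term. After the data had been seen, 2 alternatives were added because the MCF-7 WT library held counts of genes typical of HCT-116. The first subtracted an estimated HCT-116 share of 2.27% from the MCF-7 WT counts. The share is the median, as a percentage of the HCT-116 level, of the MCF-7 WT level less the MCF-7 BSL level over 49 genes with at least 50 CPM in HCT-116 and under 0.3 CPM in MCF-7 BSL, limits that were also chosen after the values were seen. The second left out genes at least 10-fold higher in HCT-116 than in MCF-7 BSL.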

Results

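Bulk RNA sequencing was available for 4 libraries from HCT-116 and MCF-7 cells, with 1 WT and 1 BSL library per line. Fragments assigned to genes numbered 15412089 in HCT-116 WT, 14196777 in HCT-116 BSL, 17662659 in MCF-7 WT and 14105467 in MCF-7 BSL. As the codes were read here, the design compares full-length p53β with its stop-lost form, within each line and across both lines. The labels do not settle that reading for WT. Ratios below are BSL over WT on the log2 scale, with 95% counting intervals in brackets, and the differences within a line have no replicate check.

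TP53, the gene whose p53β form was introduced per the series design, was counted in every library (ENSG00000141510.18, chromosome 17, 7661779 to 7687550, GRCh38). In HCT-116 it stood at 87.5 CPM in WT and 114.0 CPM in BSL, a log2 ratio of 0.38 (0.28 to 0.49). In MCF-7 the levels were 90.1 and 88.9 CPM, a ratio of -0.02 (-0.13 to 0.09). These gene counts do not separate the introduced transcript from the cells' own TP53. Without a library known to be untransduced, they also cannot show whether TP53 was overexpressed in any library. MDM2, the ubiquitin ligase that p53 induces and that degrades p53, was at 316 and 366 CPM in HCT-116 (0.22, 0.16 to 0.27) and at 224 and 206 CPM in MCF-7 (-0.12, -0.19 to -0.05). CDKN1A, which encodes the cell cycle inhibitor p21, was at 158 and 170 CPM in HCT-116 (0.11, 0.03 to 0.19) and at 31.3 and 34.0 CPM in MCF-7 (0.12, -0.06 to 0.30). None of the 3 genes passed the edgeR test across lines, each with a Benjamini-Hochberg adjusted p of 0.999.

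**Figure D1:**
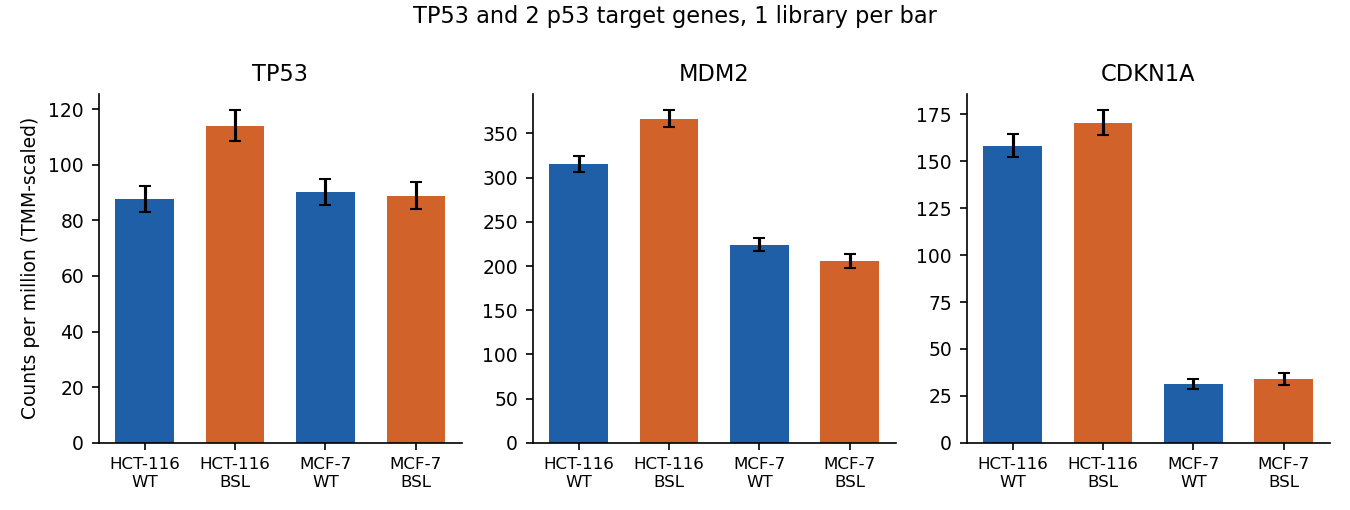
Levels of TP53, MDM2 and CDKN1A in TMM-scaled CPM, 1 bar per library, blue for WT and orange for BSL, with exact Poisson 95% intervals of the count as error bars. TP53 was higher in HCT-116 BSL (114.0 CPM) than in HCT-116 WT (87.5 CPM) and nearly level in MCF-7 (90.1 and 88.9 CPM).

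Markers of MCF-7 separated the lines, while the genes listed beforehand as HCT-116 identity genes did not. Of 25 MCF-7 identity genes, 23 reached a mean of 1 CPM in MCF-7 and 13 in HCT-116, and of 25 HCT-116 identity genes 8 reached it in MCF-7 and 7 in HCT-116. The latter list held ASCL2 and CEACAM6, with 0 counts in both HCT-116 libraries and 54.8 and 9.55 CPM in MCF-7 WT, and also EREG, at 1316 CPM in HCT-116 WT and 32.5 CPM in MCF-7 WT. ASCL2, CEACAM6, ESR1, GATA3, SIX1 and the fibroblast and endothelial markers named here were singled out after their values were seen. ESR1, the oestrogen receptor gene, was at 364 CPM in MCF-7 WT and 388 CPM in MCF-7 BSL, against 0.193 and 0.0674 CPM in HCT-116 WT and BSL (edgeR Benjamini-Hochberg adjusted p = 7.73e-10 for the line term). GATA3, a luminal breast transcription factor, was at 81.5 and 90.2 CPM in MCF-7 WT and BSL and at 0.386 and 0.202 CPM in HCT-116 WT and BSL. In the edgeR fit, 5438 genes were higher in MCF-7 and 5254 were higher in HCT-116. Markers of other cell types were low. No leukocyte marker reached a mean of 1 CPM in either line. Of 12 fibroblast markers, ACTA2 and COL1A1 reached it in HCT-116 and COL1A1 in MCF-7, at up to 14.5 CPM. Of 8 endothelial markers, ESAM reached it in HCT-116 and EMCN and VWF in MCF-7, at up to 3.61 CPM. Of 10 markers of the kidney line HEK293, SIX1 alone reached it, at up to 4.45 CPM in HCT-116 and 14.6 CPM in MCF-7.

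The MCF-7 WT library also held counts of genes typical of HCT-116. Of 49 genes with at least 50 CPM in HCT-116 and under 0.3 CPM in MCF-7 BSL, 48 were higher in MCF-7 WT than in MCF-7 BSL beyond counting error, a count that the choice by a low MCF-7 BSL level favours. Among 109 HCT-116-high genes chosen by their mean over both MCF-7 libraries, 98 were higher in MCF-7 WT and 0 in MCF-7 BSL. The median level of the 49 genes in MCF-7 WT was 2.34% of the HCT-116 level (quartiles 1.73% and 3.46%). MTAP, a methionine salvage enzyme gene in a chromosome 9 segment that MCF-7 has lost, had 10.7 CPM in MCF-7 WT and 0.496 CPM in MCF-7 BSL, against 474 and 523 CPM in HCT-116 WT and BSL. CDKN2A, its neighbour, at 14.4 and 16.4 CPM in HCT-116 WT and BSL, had no detectable excess at this depth, with 0.657 CPM in MCF-7 WT and 0.709 CPM in MCF-7 BSL, a ratio of 0.09 (-1.28 to 1.48). These genes were picked after their values were seen. HCT-116 WT showed no counterpart of similar size. There, 58 genes high in MCF-7 and under 0.3 CPM in HCT-116 BSL had a median of 0% of their MCF-7 level. That median does not exclude a smaller share.

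**Figure D2:**
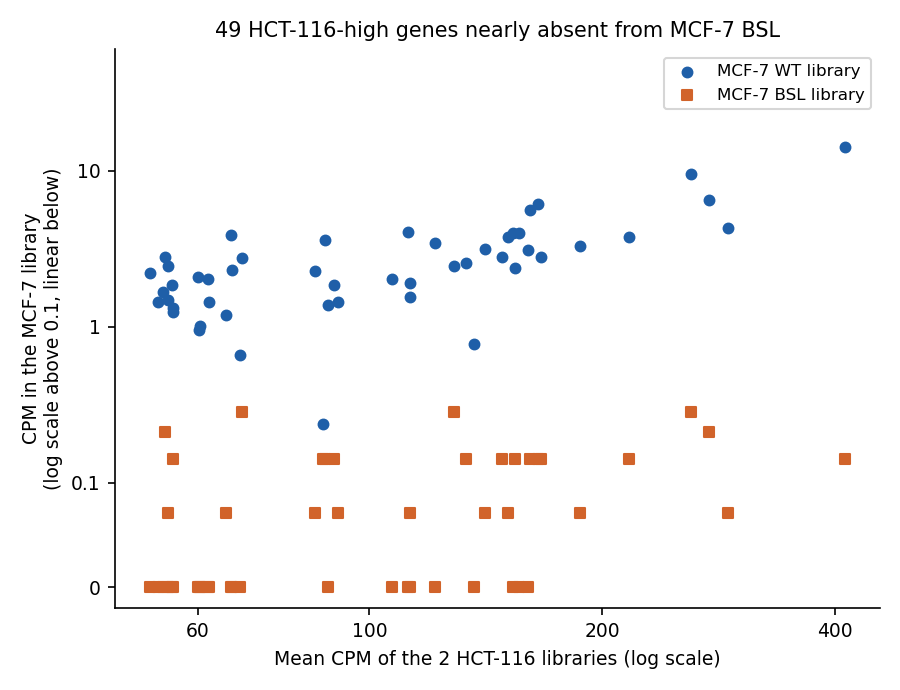
Levels of 49 genes chosen for at least 50 CPM in HCT-116 and under 0.3 CPM in MCF-7 BSL, with the mean CPM of the 2 HCT-116 libraries on the horizontal axis (log scale) and the CPM in MCF-7 WT (blue circles) or MCF-7 BSL (orange squares) on the vertical axis (log above 0.1, linear below). The MCF-7 WT points lie at a median of 2.34% of the HCT-116 level.

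In HCT-116, genes of the unfolded protein response, which restores protein folding in the endoplasmic reticulum, were lower in BSL. All 21 measured members had a negative ratio, with a median of -0.34 at percentile 0 of random lists, and 4 were at least 1.5-fold lower. HSPA5, the endoplasmic reticulum chaperone BiP, went from 296 CPM in WT to 128 CPM in BSL, a ratio of -1.21 (-1.29 to -1.13). CREB3L2, a transcription factor of the same response, was at -1.02 (-1.29 to -0.77), HERPUD1 at -0.70 (-0.89 to -0.51) and MANF at -0.64 (-0.80 to -0.49). In MCF-7 the list median was -0.04 at percentile 69.6, and 0.04 with total counts. There HSPA5 was at 0.04 (-0.04 to 0.13) and XBP1, a transcription factor of the response, at -0.25 (-0.26 to -0.23). Across lines, 3 of the 21 fell by edgeR adjusted over the list alone and 0 over all genes tested.

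Replication-dependent histone genes were also lower in HCT-116 BSL, with 30 of 32 members negative and a median of -0.41. In MCF-7, 38 of 42 were negative with a median of -0.12 at percentile 0.49, or -0.04 with total counts, and across lines 9 fell by edgeR adjusted over the list alone and 0 over all genes tested. In HCT-116, H3C10 was at -0.68 (-0.74 to -0.62) and H4C4 at -0.58 (-0.64 to -0.51), against -0.34 and -0.25 in MCF-7. Histone genes are near-identical copies, so their single values are uncertain. In HCT-116, genes of G1/S and DNA replication had a median of -0.08, or -0.02 with total counts. Those of G2/M and mitosis had a median of 0.10 in HCT-116, with CENPA, the centromeric histone, at 0.58 (0.39 to 0.78). The 85 measured p53 target genes had a median of 0.09 at percentile 100, or 0.15 with total counts, with 57 positive, 0 at least 1.5-fold higher and 5 at least 1.5-fold lower. PLK2 was at 0.47 (0.39 to 0.55) and NINJ1 at 0.48 (0.23 to 0.74). Their 15 measured apoptosis genes had a median of 0.12, or 0.21 with total counts, with TP53I3 at 0.35 (0.06 to 0.65). WNT target genes had a median of -0.26, led by AXIN2, a feedback inhibitor of the pathway, at -0.76 (-1.11 to -0.43), of whose exon length 25.2% overlaps another gene on its strand. TGF-β and SMAD targets had a median of -0.23, with SERPINE1 at -0.38 (-0.59 to -0.18), and epithelial genes a median of -0.20, with CDH1, the E-cadherin gene, at -0.43 (-0.59 to -0.27). In MCF-7 the WNT median was -0.05 and the TGF-β and SMAD median 0.02, both within the central 95% of random lists. The MCF-7 epithelial median was -0.15 at percentile 0.4, with 18 of 22 members negative, or -0.07 with total counts.

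By the size rule, 86 of 13304 measured genes were at least 2-fold higher and 91 at least 2-fold lower in HCT-116 BSL, where counting error alone gave 13.2 and 12.7. At a mean of at least 5 CPM, 2 of 10473 genes were higher and 9 were lower. The higher genes were IFRD1, a transcriptional regulator, at 1.01 (0.71 to 1.34), and the non-coding SNHG20, named after its value was seen. The 8 protein-coding lower genes were HLA-A, MT-ND2, MT1X, KCTD11, HSPA5, LOXL2, CREB3L2 and CTXN1. KCTD11 was at -1.21 (-1.57 to -0.89), LOXL2, a collagen crosslinking enzyme, at -1.04 (-1.41 to -0.71) and MT-ND2 at -1.49 (-2.01 to -1.07).

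In MCF-7, the lowest genes in BSL were largely genes that HCT-116 expresses strongly. GSTP1, a glutathione transferase, went from 14.3 CPM in MCF-7 WT to 0.142 CPM in MCF-7 BSL, a ratio of -5.72 (-9.71 to -4.78), and stood at 418 CPM in HCT-116 WT. CAV1, the caveolin gene, was at -5.68 (-7.75 to -4.89) in MCF-7, EREG, an EGF receptor ligand, at -4.05 (-4.77 to -3.58) and AKAP12 at -3.17 (-3.39 to -2.98). Once the HCT-116 share was subtracted, EREG was at -0.33 and AKAP12 at -0.62, while GSTP1 was at -4.23 and CAV1 at -4.68. The same median share was taken off every gene. The 49 genes chosen above ran from 0.27% to 5.86% of their HCT-116 level in MCF-7 WT, with GSTP1, among them, at 3.46%. Genes above the subtracted share keep a negative ratio, so the values of GSTP1 and CAV1 do not show a fall beyond HCT-116 RNA. Of the 269 genes at least 2-fold lower in MCF-7 BSL, 98 were at least 10-fold higher in HCT-116 than in MCF-7 BSL.

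Genes higher in MCF-7 BSL included METRNL, a secreted factor, at 0.597 CPM in WT and 9.85 CPM in BSL, a ratio of 3.78 (3.12 to 5.14). TM4SF1, a membrane protein, was at 2.11 (1.73 to 2.60), COL12A1, a collagen, at 1.95 (1.48 to 2.57), TNFRSF11B, the decoy receptor osteoprotegerin, at 1.81 (1.35 to 2.41) and NPY1R, a neuropeptide Y receptor, at 1.36 (1.15 to 1.57). MGP, a matrix protein that inhibits calcification, was at 1.17 (0.92 to 1.44) and THBD, thrombomodulin, at 1.16 (0.69 to 1.70). With the HCT-116 share removed, the ratios of METRNL and COL12A1 were higher still, since that share took most of their MCF-7 WT counts, while TM4SF1 was at 2.10, TNFRSF11B at 1.80 and NPY1R at 1.35. Mesenchymal and matrix genes had a median of 0.23 over 15 measured members, of which 4 were at least 1.5-fold higher and 3 at least 1.5-fold lower. SERPINE1 was at 0.71 (0.26 to 1.19) and THBS1, thrombospondin, at 0.56 (0.51 to 0.62). Genes of NRF2 and oxidative stress had a median of 0.08 at percentile 99.98, or 0.16 with total counts, with 5 of 24 at least 1.5-fold higher. Among them HMOX1, haem oxygenase, was at 0.89 (0.74 to 1.06) and SLC7A11, the cystine transporter, at 0.61 (0.44 to 0.79). In HCT-116 the list median was -0.10 at percentile 2.8, with HMOX1 at -0.35 (-0.63 to -0.08) and SLC7A11 at -0.27 (-0.45 to -0.10), and the difference between the lines was not tested.

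Interferon response genes were lower in MCF-7 BSL, with a median of -0.30 over 32 members, 24 negative and 7 at least 1.5-fold lower. IFI27 was at -1.52 (-2.20 to -0.99), HERC6 at -1.14 (-1.62 to -0.73) and IFI6 at -0.90 (-1.15 to -0.67). With the HCT-116 share removed the list median was -0.27. Cell adhesion and signalling genes had a median of -0.37, and -0.18 once that share was removed. Within that list ANXA1 moved from -2.80 to -0.47, while PLAUR, the urokinase receptor, was at -1.03 before and -0.98 after. The 80 measured p53 target genes had a median of -0.05 at percentile 39.6, and 0.03 with total counts. Among them TSKU was at -0.75 (-0.85 to -0.64) and GDF15 at -0.72 (-0.91 to -0.53). G2/M genes had a median of -0.08 at percentile 18.75, and 0 with total counts.

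By the size rule, 122 of 13342 measured genes were at least 2-fold higher and 269 at least 2-fold lower in MCF-7 BSL, where counting error alone gave 10.78 and 14.98. At a mean of at least 5 CPM the counts were 14 and 49 of 10433 genes. Without genes at least 10-fold higher in HCT-116 than in MCF-7 BSL, 171 genes were lower.

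**Figure D3:**
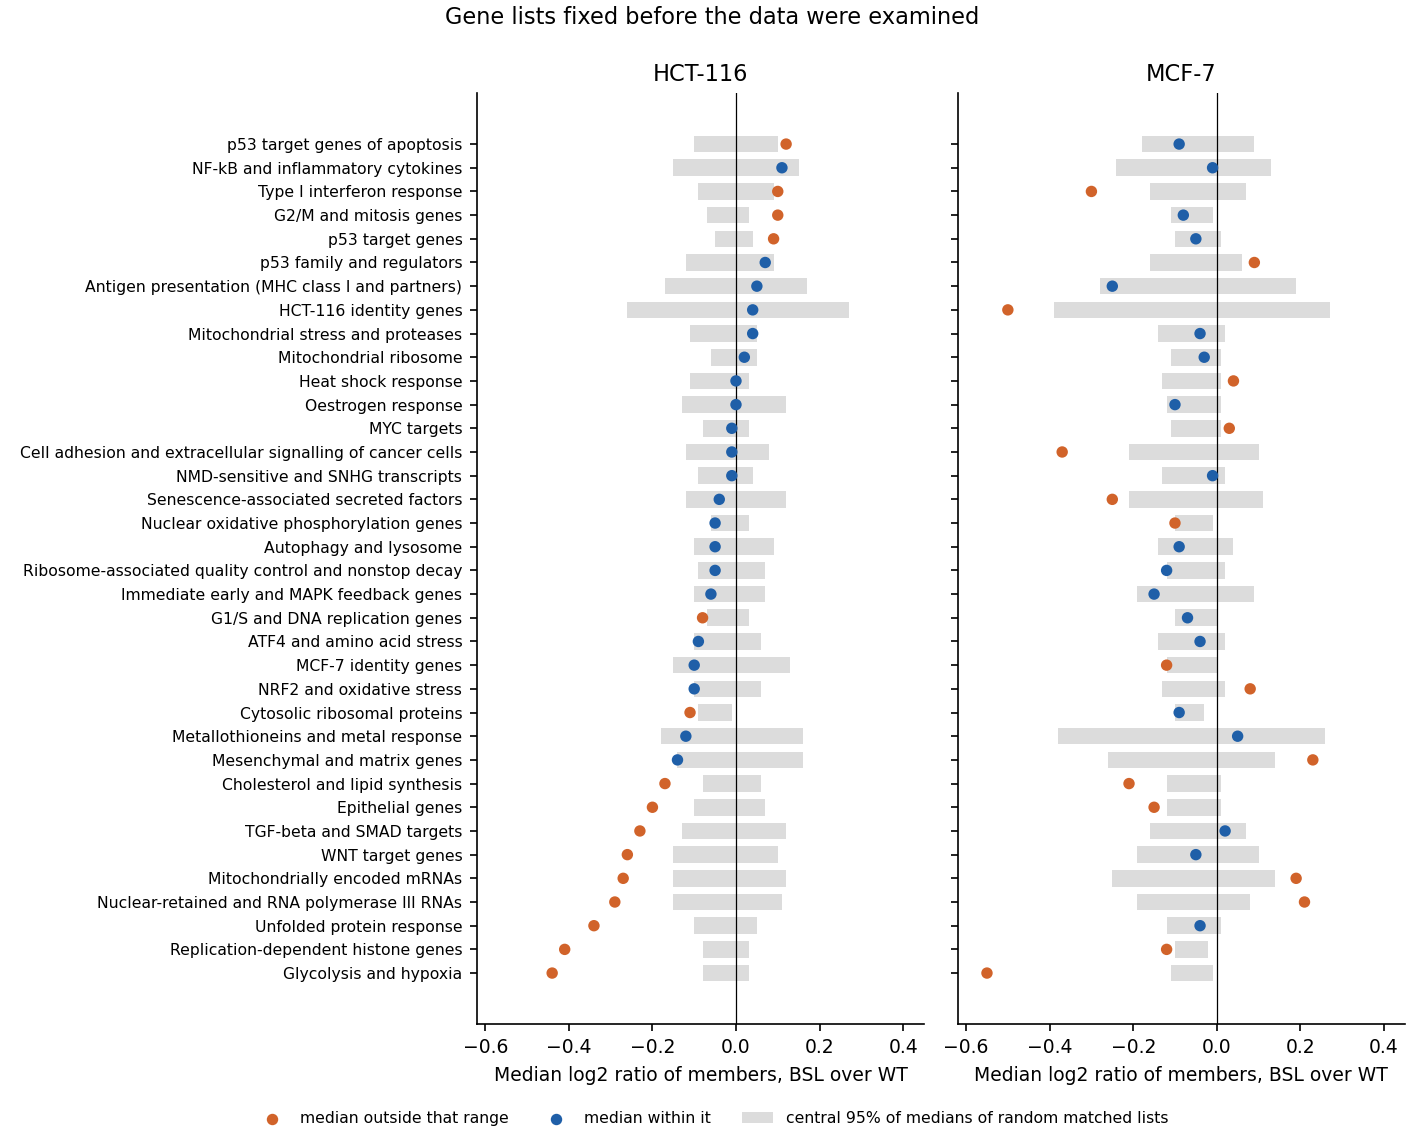
Median log2 ratio of BSL over WT for 36 gene lists in HCT-116 (left) and MCF-7 (right), 1 point per list, with grey bars for the central 95% of medians of 10000 random lists matched on expression and orange points outside it. In both lines the lowest median belongs to glycolysis and hypoxia, at -0.44 and -0.55. The MCF-7 medians are shown without subtracting the estimated HCT-116 share from the WT library. Orange points number 15 in HCT-116 and 17 in MCF-7.

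Across both lines, genes of glycolysis and of the response to low oxygen were lower in BSL. All 32 measured members were negative in each line, with medians of -0.44 in HCT-116 and -0.55 in MCF-7, each at percentile 0 of random lists, and -0.53 in MCF-7 once the HCT-116 share was removed. With total counts they were -0.39 and -0.47. In the edgeR test with Benjamini-Hochberg adjustment 11 of the 32 fell over all genes tested, and 30 of the 32 adjusted over the list alone. NDRG1, a hypoxia-induced growth regulator (chromosome 8, 133237171 to 133302022), fell by 1.10 ± 0.10 (log2, SE; edgeR Benjamini-Hochberg adjusted p = 0.011). The aldolase gene ALDOC (chromosome 17, 28573115 to 28577264) fell by 1.09 ± 0.11, with the same edgeR adjusted p of 0.011. BNIP3 and BNIP3L, mitophagy receptors, fell by 0.76 ± 0.08 and 0.78 ± 0.08 (edgeR Benjamini-Hochberg adjusted p = 0.011 and 0.0124). The glycolytic enzyme genes GAPDH, ENO1, LDHA, PGK1, GPI and PKM fell by 0.55, 0.47, 0.49, 0.71, 0.54 and 0.41, and PFKFB4, a regulator of phosphofructokinase, fell by 0.72, with edgeR Benjamini-Hochberg adjusted p of at most 0.0279. GPI, PGK1 and PKM were named after their values were seen. GAPDH stood at 5638 and 4145 CPM in HCT-116 WT and BSL and at 6033 and 3809 CPM in MCF-7 WT and BSL. CA9, the hypoxia-induced carbonic anhydrase, was at -1.07 (-1.82 to -0.46) in HCT-116 and -1.68 (-2.08 to -1.34) in MCF-7, and its edgeR Benjamini-Hochberg adjusted p was 0.212.

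The edgeR test called 15 genes lower and 0 higher in BSL among 15403, with 502 lower and 166 higher at an unadjusted p under 0.05. Together those genes are a smaller share of the genes tested than the 0.05 that no effect would give. With DESeq2 size factors 411 were lower and 228 higher, so their balance depends on scaling. The 4 called genes outside the glycolysis and hypoxia list were SCD, DDIT4, HLA-A and PLOD2, the last named after its values were seen. SCD, the stearoyl-CoA desaturase of fatty acid synthesis (chromosome 10, 100347124 to 100364834), fell by 0.73 ± 0.06 (edgeR Benjamini-Hochberg adjusted p = 0.011). DDIT4, an inhibitor of mTOR signalling, fell by 0.68 ± 0.08 (edgeR Benjamini-Hochberg adjusted p = 0.0166), and PLOD2, a collagen lysyl hydroxylase, by 0.68 ± 0.09 (0.0476). HLA-A, a class I antigen presentation gene, had counts of 166 and 8 in HCT-116 WT and BSL and of 62 and 1 in MCF-7 WT and BSL. Near-identical paralogs, and any related sequence in a vector, cannot be checked from gene counts, which leaves that value uncertain. Cholesterol and lipid synthesis genes had medians of -0.17 in HCT-116 and -0.21 in MCF-7, or -0.11 and -0.13 with total counts. SCD alone among their 31 genes fell over all genes tested, and 5 of the 31 fell adjusted over the list alone. INSIG1, a sterol-regulated brake on lipid synthesis, was at -0.54 (-0.74 to -0.34) in HCT-116 and -0.38 (-0.46 to -0.31) in MCF-7. The 15 calls rest on 1 residual degree of freedom and on spread pooled over genes. DESeq2 called 49 genes lower and 6 higher, among 6146 genes tested against 15403 in edgeR. With limma-voom 0 genes were called in either direction. Without the cell line term edgeR also called 0. Differences between the lines then enter the spread, so that count says little about the 15 calls.

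No gene rose across lines by the edgeR test, against 166 at an unadjusted p under 0.05, 6 by DESeq2 and 0 by limma-voom. IL6R, the interleukin-6 receptor gene, was at 0.57 (0.26 to 0.90) in HCT-116 and 0.80 (0.46 to 1.16) in MCF-7, and its edgeR Benjamini-Hochberg adjusted p was 0.894. MAN2A2, a Golgi mannosidase gene, was at 0.50 (0.30 to 0.72) and 0.57 (0.40 to 0.74). MAP3K5, the stress kinase gene ASK1, was at 0.45 (0.28 to 0.62) and 0.44 (0.30 to 0.58). At least 2-fold in both lines, 4 of 11820 genes were higher and 4 were lower, where independent lists would share 0.205 and 0.903. The higher genes were JHY, MAGEE1, AARSD1 and the non-coding ENSG00000271789, each under 4 CPM in every library. The lower genes were CA9, HLA-A, SAP30-DT and the non-coding ENSG00000232545. Apart from CA9 and HLA-A, these genes were named after their values were seen, and 34.2% of the exon length of AARSD1 overlaps another gene on its strand. Over the 11820 genes the ratios of the lines had a Pearson correlation of 0.0496 and a Spearman correlation of 0.0619 across genes, which are not independent replicates. Within the 32 glycolysis and hypoxia genes the Pearson correlation was 0.623.

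**Figure D4:**
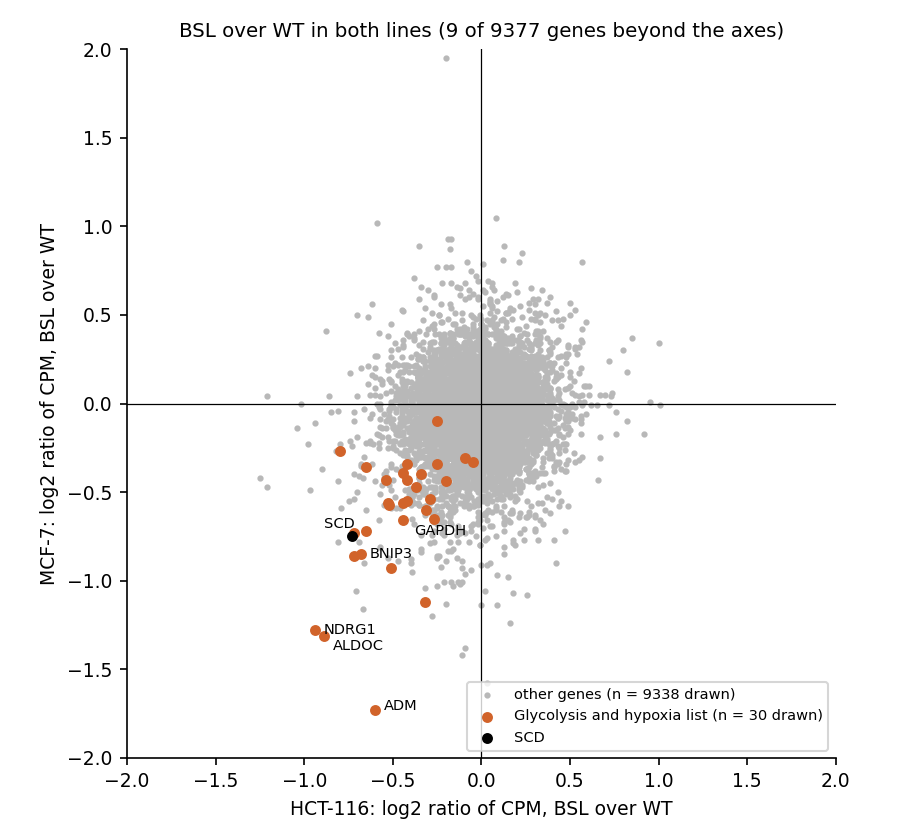
Log2 ratio of BSL over WT in HCT-116 (horizontal) and MCF-7 (vertical), 1 point per gene with a mean of at least 5 CPM in both lines (9377 genes, of which 9 lie beyond the axes). Orange points are 30 members of the glycolysis and hypoxia list, all negative in both lines, and the black point is SCD at -0.73 and -0.75.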

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

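The tests on genes typical of HCT-116, on MTAP, on the HCT-116 share and on cell density were chosen after the result or the data were seen, unlike those on scaling and GC content of the glycolysis genes.

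TXNDC5, a disulfide isomerase of the endoplasmic reticulum, had opposite ratios in the lines, -1.12 in HCT-116 and 1.98 in MCF-7. The difference between the lines was not tested, and 60.6% of the exon length of TXNDC5 overlaps another gene on its strand. The medians of 3 gene lists also lay outside the central 95% of random lists in opposite directions, and these differences were not tested either. Interferon response genes had a median of 0.10 in HCT-116 and -0.30 in MCF-7. Mitochondrially encoded mRNAs had a median of -0.27 in HCT-116 and 0.19 in MCF-7, with MT-CYB at -0.23 (-0.43 to -0.03) and 0.46 (0.12 to 0.82), though reads shared with nuclear copies leave these values uncertain. Nuclear-retained and RNA polymerase III RNAs had a median of -0.29 in HCT-116 and 0.21 in MCF-7, over 9 and 11 measured members, or -0.11 and 0.19 at a mean of at least 5 CPM.

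The MCF-7 WT library held counts of genes that HCT-116 expresses and MCF-7 BSL nearly lacks. HCT-116 RNA or cells in that library may account for them, since among 109 HCT-116-high genes picked by their mean over both MCF-7 libraries 98 were higher in MCF-7 WT and 0 were higher in MCF-7 BSL beyond counting error. The tables argue against misassigned reads of the sequenced HCT-116 WT library as the whole source, because chi-square per degree of freedom against 1 fixed share was 8.33, where a thinned HCT-116 BSL library gave at most 2.76. If HCT-116 RNA were the only source, that spread would also mean that it did not match the profile of the sequenced dishes. A construct effect does not account for MTAP, whose ratio was -4.11 (-5.76 to -3.36), on the background knowledge that MCF-7 has lost that gene, but for the other genes it cannot be told apart from HCT-116 RNA, since the Spearman correlation of 0.665 between their MCF-7 WT and HCT-116 levels leaves both open.

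Glycolysis and hypoxia genes were lower in BSL in both lines. The HCT-116 share does not account for it, since the MCF-7 median was -0.53 with that share removed, below the central 95% of random lists. With total counts the median nearest to 0 of the 2 lines was -0.39. Total counts shifted all genes by a median of only 0.05 in HCT-116 and 0.08 in MCF-7. That change was too small to bring the medians near 0, so it tests no other scaling. GC content and expression level do not account for the difference, since the median nearest to 0 was -0.40 once a trend on them was removed. A difference in density or oxygen supply between dishes cannot be told apart from an effect of the construct, which stays open, because each construct has 1 library per line. On the premise that a denser dish has fewer dividing cells, a denser WT dish would raise the G2/M median. That median lay above random lists in HCT-116 (0.10) and within them in MCF-7 (-0.08). The G1/S and histone medians were negative, at -0.08 and -0.41 in HCT-116 and at -0.07 and -0.12 in MCF-7. These cell cycle lists went in different directions in HCT-116, so they do not decide it.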

How the results depend on the processing

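The alternatives that use the HCT-116 share, or leave out genes by their HCT-116 level, were chosen after the data were seen. With DESeq2 size factors and with total counts, each count of 2-fold genes stayed within 1.5 times its main value, and so did the edgeR count of lower genes with DESeq2 size factors (13). For the values below that did not, the cause was not tested unless stated. At a mean of at least 5 CPM, where fewer genes are tested, 2 genes were at least 2-fold higher and 9 lower in HCT-116 BSL, 14 higher and 49 lower in MCF-7 BSL, and 0 higher and 0 lower in both, with a correlation of BSL over WT log2 ratios between lines of 0.0953. With no filter, which adds genes of few counts, these were 1855 and 1201 in HCT-116 and 194 and 106 in both, with a correlation of 0.00736. The number of MCF-7 genes at least 2-fold lower in BSL was then 1926, against 1949 higher, and edgeR called 10 higher and 112 lower. A prior count of 10, which shrinks ratios of low counts, gave 23 and 34 in HCT-116, 51 and 168 in MCF-7, and 0 and 1 in both, and a prior count of 0.5 gave 7 higher in both. Among protein-coding genes alone, 43 were higher and 55 lower in HCT-116, 74 were higher in MCF-7 and 2 were lower in both. Leaving out genes at least 10-fold higher in HCT-116 than in MCF-7 BSL gave 171 lower in MCF-7.

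Across lines, DESeq2 called 6 genes higher and 49 lower among 6146 tested, sharing 14 of the 15 edgeR calls, and limma-voom called 0 lower. Without the cell line as replicate block, where differences between the lines enter the spread, edgeR called 0 lower. With the HCT-116 share removed, edgeR called 2 higher (NRCAM and NPY1R, named after the fact) and 34 lower, which held all 15 calls. NPY1R had 0 counts in both HCT-116 libraries, so its call rests on the MCF-7 libraries alone. With DESeq2 size factors 13 of the 15 were called, and with a robust fit 14. Leaving out a library leaves no residual degree of freedom, so no such test was made. Subtracting the HCT-116 share reversed MTAP, to 2.26, and ALDH1A3, to 4.70, because 1 fixed share took away more than those genes had. The same subtraction moved 18 of the other named ratios and 2 list medians beyond their intervals. Total counts moved 73 named ratios and 18 list medians, with a shift of all genes by a median of 0.05 in HCT-116 and 0.08 in MCF-7. A level of 0 allows up to 0.213 CPM, so differences between genes below it were not detectable at this depth.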

Other observations

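Cytosolic ribosomal protein genes had medians of -0.11 in HCT-116 and -0.09 in MCF-7, with 52 and 54 of 57 members negative and 0 at least 1.5-fold lower in either line. The MCF-7 median was at percentile 3.5, within the central 95% of random lists, and all measured MCF-7 genes had a median of -0.045. With total counts the ribosomal medians were -0.06 and -0.02. Nuclear oxidative phosphorylation genes had medians of -0.05 and -0.10 over 53 members, or 0 and -0.02 with total counts. In MCF-7, heat shock genes had a median of 0.04, MYC targets 0.03 and p53 family genes and regulators 0.09, against 0, -0.01 and 0.07 in HCT-116. With total counts the MCF-7 medians were 0.12, 0.11 and 0.17. Senescence-associated secreted factors had medians of -0.04 in HCT-116 and -0.25 in MCF-7, and the genes listed as HCT-116 identity genes 0.04 and -0.50, although 7 of the 25 reached 1 CPM in HCT-116 and 8 in MCF-7. With the HCT-116 share removed from MCF-7 WT, an alternative chosen after the data were seen, these MCF-7 medians were -0.15 at percentile 5.21 and -0.36 at percentile 3.16, both within the central 95% of random lists. MCF-7 identity genes had medians of -0.10 and -0.12.

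Medians lay within the central 95% of random lists in both lines for the lists that follow, in the order HCT-116 and MCF-7. They were 0.05 and -0.25 for antigen presentation, 0.11 and -0.01 for NF-kB and inflammatory cytokines, -0.09 and -0.04 for ATF4 and amino acid stress, and 0.04 and -0.04 for mitochondrial stress. Mitochondrial ribosome genes had 0.02 and -0.03, autophagy and lysosome genes -0.05 and -0.09, and oestrogen response genes 0 and -0.10. Immediate early genes had -0.06 and -0.15, transcripts sensitive to nonsense-mediated decay -0.01 and -0.01, ribosome quality control and nonstop decay genes -0.05 and -0.12, and metallothioneins -0.12 and 0.05.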
